A study of Homo sapiens with 6 samples.

How the data were processed

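Gene expression was measured on 6 oligonucleotide arrays, 1 for each of 6 groups of human melanoma cells. The groups were untreated WM793, WM793 with 5-aza-2′-deoxycytidine (DAC, 2 µg/ml), WM793-P1N1 with DAC, WM793-P2N1 with DAC, untreated 1205-Lu and 1205-Lu with DAC. Groups were taken from the sample titles, and the arrays called untreated are those whose labels name no treatment. Untreated WM793-P1N1 and WM793-P2N1 cells were not analysed here.

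The authors deposited 1 linear intensity per probe set, with 7129 probe sets per array. The software that made the intensities, its settings and its handling of background are not given in the sources used here. The mean intensity after removal of the highest and lowest 2% of probe sets lay between 40.0452 and 40.0607 on the 6 arrays, so that the deposited intensity values had been brought to a common mean. The array medians still ranged from 8.3 to 11.6, a spread of 0.48 on the log2 scale. By a rule set on that spread (values as deposited within 0.1, quantile normalization otherwise), the arrays were quantile normalized, which moved array medians by at most 0.26 on the log2 scale. Values under the 20th percentile of all normalized intensities (1.93) were set to that floor, and log2 was taken. The floor lies below the brightest of the dim bacterial controls on every array but treated WM793 (1.8 as deposited). A log2 difference from a value at the floor is therefore set by the floor and is no bound on the fold.

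Probe sets were named through the platform annotation held by the public repository. Of the probe sets, 5709 had 1 gene symbol, 321 had several and were not named, and 1099 were not listed. After removal of the 58 control probe sets, 5694 probe sets remained for 4993 genes, and a gene with several (572 genes) was represented by the probe set with the highest mean. Entrez identifiers of 5689 probe sets were found in a RefSeq table (assembly GRCh38.p14, used for names and gene lengths), and 0 symbols needed an update. No genome build is attached to the array values, so no coordinates are given. Genes of the Y chromosome and XIST are not named. The values of some control probe sets are not reported here.

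Each group is a single array, so no comparison of a pair of arrays has a replicate or a p-value, and the number of arrays limits the precision of every value. Such pairs were compared by size, as 2-fold differences among genes with at least 1 array of the comparison above the floor. WM793 and 1205-Lu each had an untreated and a treated array. Those 4 arrays were fitted with limma 3.58.1 (R 4.3.3) with terms for line and treatment and Benjamini-Hochberg adjustment over 4697 genes. That fit has 1 residual degree of freedom and a prior worth 5.32, and it treats the lines as the replicates of the treatment. Its p-values therefore set the mean change over the pairs of arrays against the disagreement of those pairs and a variance pooled over genes. They say nothing of repeated cultures. Counts of genes past 2-fold in both pairs were set beside the overlap of independent lists of the same sizes. Counts that share an array were also set beside 100 simulated rounds without any effect. With no replicates, the noise of those rounds was estimated from the difference between the DAC responses of WM793 and 1205-Lu. Responses particular to 1 line therefore count as noise.

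The 18 gene lists held 810 genes, of which 520 were measured. They were interferon response, antigen presentation, cancer-testis antigens, imprinted genes, genes often methylated in tumours, melanocyte differentiation, invasion and extracellular matrix, p53 targets, cell cycle, DNA methylation machinery, metallothioneins, deoxycytidine metabolism, tumour growth factors, ribosomal proteins, germline and tissue-restricted genes, and markers of keratinocytes, leukocytes and fibroblasts. A list's median was placed among 10000 random lists of the same size matched on mean expression. Members of a list can move together while random genes need not, so a percentile describes these arrays and says nothing of repeated cultures. The terms of the limma fit were tested per list with camera at a preset correlation of 0.01, and again with an estimated correlation. The preset takes the members of a list as nearly independent. The estimate rests on the 1 residual degree of freedom of the fit, at which hardly any list can pass, so a call lost with it decides nothing. The design, the lists, the rule for naming genes and the other settings to be tried were chosen before the data were examined.

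Genes named are, for DAC in both lines and for 1205-Lu against WM793, the 10 per direction with the largest mean change among those past 2-fold in both pairs and above the floor, and up to 5 per direction with a value at the floor. For each list they are up to 4 members past 2-fold in both pairs, or otherwise the 2 with the largest mean change. For each single comparison and for the difference in response they are the 5 with the largest change per direction, and for restored genes the 10 with the largest change. DNMT1, DNMT3A and DNMT3B were to be named in any case, and DNMT1 is the member measured here.

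The procedure was tested on simulated data for DAC in both lines, with 200 of 4993 genes changed over 20 rounds and a noise SD of 0.44. limma recovered 13.4% of genes changed 2-fold, 72.3% of those changed 4-fold and 81.1% of those changed 8-fold, and called 0.107% of unchanged genes. The rule of 2-fold in both lines recovered 20% at 2-fold and 72.4% at 4-fold and took in 0.397% of unchanged genes. That test used the same noise for all genes, while the noise estimated from the arrays was 0.70 to 0.72 for genes with mean intensities from 2.60 to 8.74. These rates are therefore too favourable for dim genes. Genes of equal variance also suit the prior of limma. On the arrays limma called 1 gene higher with DAC, and BST2, with a mean log2 change of 2.28, had an adjusted p of 0.30 in that fit. The simulated limma rates therefore do not carry over to the arrays, for brighter genes as well. All these noise values come from the difference between the DAC responses of the lines, not from replicates. Alternatives were other scalings, floors, filters, fold thresholds, designs and variance priors, the mean of all probe sets of a gene, and each pair of arrays alone. Figures were drawn with matplotlib 3.10.9.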

Results

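The arrays compared cells of a melanoma progression model with and without 5-aza-2′-deoxycytidine (DAC), a nucleoside analogue that traps DNA methyltransferases and lowers DNA methylation. WM793 is a line from a primary melanoma. WM793-P1N1, WM793-P2N1 and 1205-Lu are more aggressive derivatives of it, selected in nude mice, the last from lung metastases. DAC was given at 2 µg/ml, and each of the 6 groups is 1 array of 7129 probe sets with no replicate. The design asks which genes respond to DAC in WM793 and in 1205-Lu, how these lines differ, and how the treated derivatives differ from treated WM793. The intensity of the probe sets had a median between 8.3 and 11.6 per array. The 15 probe sets for bacterial RNAs that stayed dim reached 12.4 on the treated WM793-P1N1 array and between 1.8 and 7.6 on the others. Values at or below such levels are hard to tell from background. A log2 difference from such a value is a size from dim signal rather than a measured fold.

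The arrays also differed in quality measures, some of which follow treatment. The ratio of the actin control's 3′ to 5′ probe sets was 4.72 on the untreated WM793 array and 1.56 on the treated one, and 2.07 and 1.05 on the untreated and treated 1205-Lu arrays. It was 1.497 for treated WM793-P1N1 and 1.28 for treated WM793-P2N1. The 9 bacterial spike probe sets had geometric mean intensities of 202 and 207 on the untreated WM793 and 1205-Lu arrays, against 125 and 57.1 on the treated ones. The GAPDH control had 3′ to 5′ ratios of 1.37 and 1.23 on the untreated and treated WM793 arrays and of 0.877 and 0.936 on those of 1205-Lu, so it did not follow the actin ratio in 1205-Lu. These differences stand beside every treatment comparison that follows.

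With DAC, genes of the interferon response were higher in both WM793 and 1205-Lu. IFI27, an interferon-induced mitochondrial protein, went from 8.30 to 662 in WM793 and from the floor to 633 in 1205-Lu, with log2 changes of 5.05 and 4.98 when the floor is set at intensity 20. ISG15, a ubiquitin-like protein, went from 92.7 to 1239 and from 27.1 to 194. MX1, an antiviral GTPase, went from 83.5 to 364 and from 7.90 to 328, and IFITM1, a membrane protein that restricts viral entry, from 114 to 909 and from 39.7 to 234. IFIT1 went from 14.5 to 208 in WM793 and from the floor to 12.8 in 1205-Lu, where no change was left with the floor at 20 (0.00, against 3.38 in WM793).

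The interferon list had 41 measured members, 15 past 2-fold higher in both lines and 1 (GBP2) past 2-fold lower in both. Its median log2 change was 1.34 in WM793 and 0.90 in 1205-Lu, each above all 10000 random lists (percentile 100). limma passed 1 member over all genes tested and 19 members adjusted over the list alone, 18 of them higher. In camera the list moved up with an adjusted p of 1.9e-12 at the preset correlation, which takes its members as nearly independent. With an estimated correlation, at 1 residual degree of freedom, the adjusted p was 0.78, which decides nothing. The percentiles and the camera p-values say nothing of repeated cultures. The medians exceeded 0.5 under every scaling tried, and the treated array of each line had the lower actin 3′ to 5′ ratio.

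**Figure D1:**
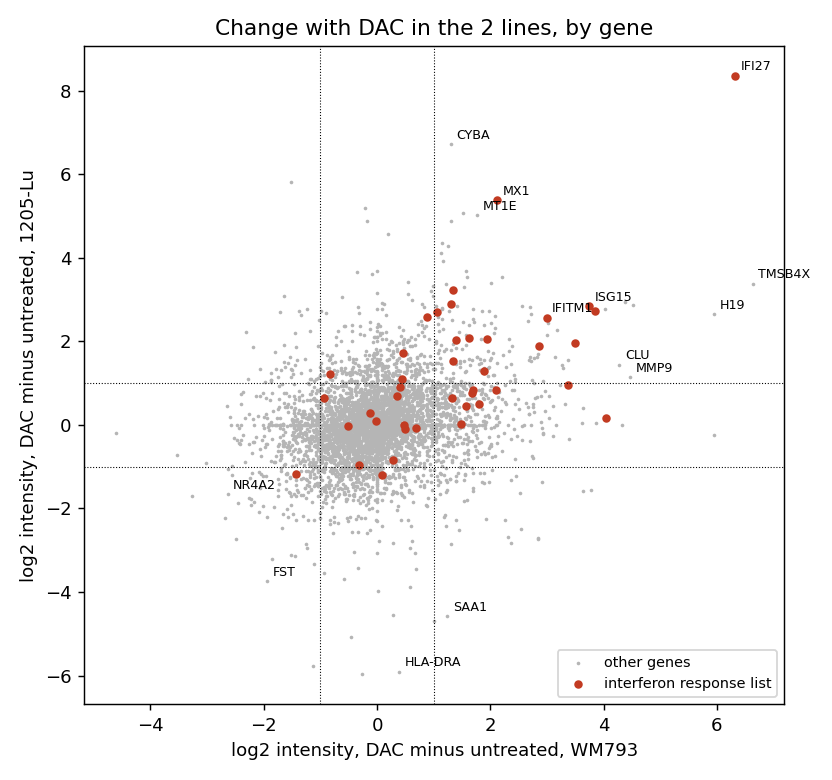
Log2 intensity difference, DAC-treated minus untreated, for each measured gene in WM793 (x axis) and in 1205-Lu (y axis), with the 41 interferon list members in red and dotted lines at 2-fold. IFI27 lies at 6.32 in WM793 and 8.35 in 1205-Lu, and HLA-DRA lies at 0.39 in WM793 and -5.91 in 1205-Lu.

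**Figure D2:**
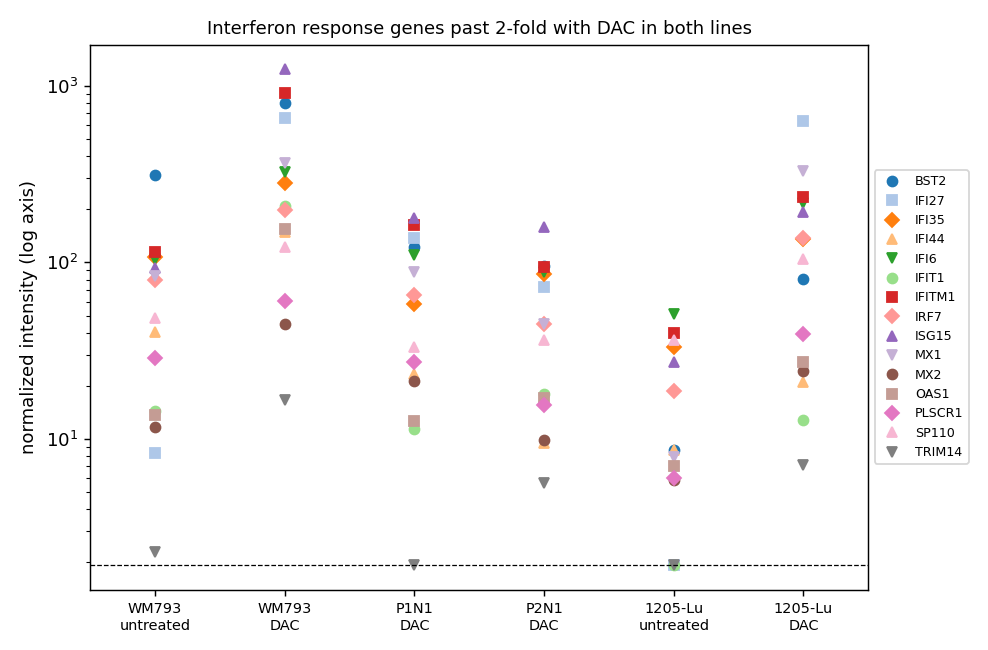
Normalized intensity (log axis) of the 15 interferon list members past 2-fold with DAC in both lines, on each of the 6 arrays, with the floor of 1.93 as a dashed line; each point is 1 array. ISG15 stands at 1239 on the treated WM793 array and at 179 and 160 on the treated WM793-P1N1 and WM793-P2N1 arrays.

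Outside that list, CYBA, a subunit of the NADPH oxidase, went from 452 to 1112 with DAC in WM793 and from 3.81 to 400 in 1205-Lu. The imprinted RNA H19 went from the floor to 119 in WM793 and from 29.8 to 186 in 1205-Lu, and TMSB4X, an actin-binding peptide, from the floor to 191 and from 2.05 to 21.4. CKB, a creatine kinase, went from 2.30 to 47.9 and from 3.43 to 26.3, and the chaperone CLU had changes of 4.28 and 1.44. The secreted proteins IGFBP5 (from the floor to 44.2 in WM793 and from 4.28 to 31.5 in 1205-Lu) and SPP1 (from the floor to 31.6 and 13.2), the gelatinase MMP9 (log2 changes of 4.47 and 1.14) and the metallothionein MT1E (1.77 and 5.02) were also past 2-fold in both lines. The peptide hormone ADM (1.51 and 5.08) and the immediate early gene ARC (1.31 and 4.88) had larger changes in 1205-Lu. Many of these untreated values were dim, and with the floor at intensity 20 the changes were 1.26 and 0.39 for CKB, 1.35 and 1.14 for MMP9, 2.58 and 2.64 for H19, 1.14 and 0.66 for IGFBP5, 0.66 and 0.00 for SPP1, 3.26 and 0.10 for TMSB4X, 0.00 and 1.80 for ADM and 0.25 and 2.28 for ARC.

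Genes lower with DAC in both lines included FST, an activin antagonist, from 103 to 26.9 in WM793 and from 189 to 14.2 in 1205-Lu. The nuclear receptor NR4A2 went from 131 to 21.0 and from 56.1 to 17.8, the cytokine IL24 from 183 to 84.4 and from 145 to 14.4, and the receptor phosphatase PTPRZ1 from 79.8 to 25.1 and from 66.2 to 11.9. COL15A1 (log2 changes of -2.08 and -2.08), ABCB4 (-2.27 and -1.74), AFF3 (-2.22 and -1.78), DELE1 (-1.45 and -3.15), MAL (-1.93 and -2.21) and NELL1 (-1.52 and -3.12) followed. ART3, COL19A1 and CPN1 went from 105, 12.8 and 17.8 to the floor in 1205-Lu and had log2 changes of -1.12, -2.49 and -1.86 in WM793. With the floor at 20 their changes in 1205-Lu were -2.39, 0.00 and 0.00. ERCC8 and IL16 reached the floor on the treated WM793 array. With the floor at 20, FST, NR4A2, IL24 and PTPRZ1 stayed past 2-fold in both lines, and COL15A1, ABCB4, AFF3, DELE1, MAL and NELL1 did not.

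By size, 615 genes were past 2-fold higher and 542 lower with DAC in WM793, and 562 and 525 in 1205-Lu. Both lines shared 152 higher genes, against 73.6 for independent lists, and 112 lower genes, against 60.6, while 105 genes went opposite ways, against 134. The changes of the lines had a Pearson correlation of 0.258 across 4697 genes, which are not independent replicates. limma called 1 gene, IFI27, higher at an adjusted p of 0.0485 (mean log2 change 7.34, SE 0.58, higher in both lines, with the floor standing for untreated 1205-Lu), and 0 lower. IFI27 kept a mean log2 change between 5.02 and 7.87 over other scalings, floors and probe set rules, but limma called 0 genes higher under 5 of 11 other settings, among them median scaling and the lower floor. At an unadjusted p under 0.05, limma had 288 genes higher and 213 lower, where 235 in all are due by chance.

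Values as deposited gave 466 genes higher and 709 lower in 1205-Lu (39.7% higher, against 51.7% after quantile normalization), with a median of all genes of -0.15 there, against -0.014. With a floor at intensity 20, chosen after the dim controls were seen, 43 genes were higher (13.2 for independent lists) and 30 lower (9.16) in both lines, and 13 of the 30 genes named for this comparison stayed past 2-fold in both.

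Among the other lists, fibroblast and stromal markers had a camera adjusted p of 0.035 upward with DAC in the limma fit. It was 0.78 with an estimated correlation, at 1 residual degree of freedom. Their 19 members had a median of 0.00 in WM793 and 0.54 in 1205-Lu, so the call rests on the mean of the lines (0.81). With values as deposited the 1205-Lu median was 0.28. In all, 3 members were past 2-fold in both. These were the collagen COL1A1 (3.17 and 2.26), the smooth muscle protein TAGLN (1.83 and 2.06) and the surface protein THY1 (1.15 and 2.79).

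Many of the cancer-testis antigens are silenced by methylation in somatic cells, but only 12 of the 79 genes in that list could be used here. Of these 12, 0 were past 2-fold in the same direction in both lines, with medians of -0.063 in WM793 and -0.67 in 1205-Lu. Most of the list is thus not covered by this result. MAGEA4 went from 6.72 to 8.20 in WM793 and from 45.6 to the floor in 1205-Lu, and MAGEA12 from 59.2 to 39.4 and from 72.3 to 5.63. Germline and tissue-restricted genes had 0 of 27 in both lines, with CGA and TFF1 at 2.11 and 1.64 in WM793 and at 0.00 and 0.51 in 1205-Lu. In WM793 the germline list had a median of 0.29 (percentile 95.3), with 9 members past 2-fold higher and 1 lower. In 1205-Lu it had 0.00 (percentile 49.3), with 1 higher and 2 lower. Of 44 genes often methylated in tumours, 6 were higher and 1 lower in both, among them SFN (3.27 and 1.42), TFPI2 (2.78 and 1.59), RARB (from the floor to 4.08 in WM793 and from 2.97 to 15.8 in 1205-Lu) and UCHL1 (from the floor to 10.3 and from 3.13 to 7.12). RARB and UCHL1 had no change in either line with the floor at 20. Their medians were 0.012 and 0.094.

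Imprinted genes had 2 of 18 members higher in both lines (H19 and TFPI2), and invasion and matrix genes 6 of 69 higher and 1 lower, with medians of 0.39 in WM793 (percentile 100) and 0.030 in 1205-Lu (percentile 67.7) and TGFBI going from 234 to 671 and from 133 to 737. Melanocyte genes had 2 of 21 lower in both: ERBB3 went from 118 to 43.6 and from 36.3 to 7.53, and EDNRB reached the floor on both treated arrays. Tumour growth factors had 1 higher and 3 lower of 46, with BMP2 at -1.20 and -1.47. Antigen presentation had medians of opposite sign, 0.42 in WM793 (percentile 99.6) and -0.31 in 1205-Lu (percentile 1.88), and 1 of 25 in both, the peptide transporter TAP1 (1.80 and 1.45). Keratinocyte markers had a median of 0.83 in WM793 (percentile 99.9), where 9 of 22 members were past 2-fold higher, and of -0.015 in 1205-Lu. In both lines 2 were higher (KRT15, from the floor to 8.87 and 22.6, and PI3, with log2 changes of 3.27 and 1.36). Leukocyte markers had 1 of 26 (LCP2), metallothioneins 1 of 10 (MT1E) and p53 targets 1 of 15 (SFN).

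Cell cycle genes had 1 of 51 higher in both lines (CDC6) and 1 lower (BRCA1, near the floor on all 4 arrays). Their medians were -0.34 in WM793 (percentile 1.31, 6 higher and 9 lower) and -0.028 in 1205-Lu (percentile 42.9, 5 higher and 4 lower). Deoxycytidine genes had 1 of 12 higher, the deaminase CDA (1.28 and 1.10), and 1 lower, the transporter SLC29A2 (-1.74 and -1.56). The DNA methylation machinery had 0 of 10, with DNMT1, the maintenance methyltransferase, at 53.5 and 36.3 in untreated and treated WM793 and at 51.5 and 50.2 in 1205-Lu, SUZ12 at -1.43 and -0.41, and TDG at -1.19 and -0.52. Ribosomal proteins had 0 of 41, with medians of -0.42 and -0.16, which were -0.97 and 0.13 with median scaling and -0.99 and -0.13 with values as deposited, and RPS25 at -1.51 and -0.70. The p53 list had a median of 0.29 in WM793, which was -0.049 with median scaling and -0.064 with values as deposited. None of these lists, which exclude the interferon and fibroblast lists, passed camera with DAC, the lowest adjusted p being 0.071 for the ribosomal proteins. That list passed downward with an adjusted p of 0.0015 under median scaling and 0.00062 with values as deposited. Its range over the settings tried was 0.00062 to 0.78, the highest with the estimated correlation.

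The response differed in size between the lines for several genes. In 1205-Lu the class II antigen presentation genes HLA-DRA, HLA-DRB1 and HLA-DPB1 went from 435, 422 and 69.2 to 7.23, 6.72 and 2.05 with DAC, while WM793 had 287, 283 and 31.1 untreated and 375, 235 and 22.6 treated. CD74, the class II invariant chain, went from 460 to 17.8 in 1205-Lu and from 100 to 201 in WM793. The acute phase protein SAA1 went from 1204 to 50.2 and from 414 to 980. Some HLA probe sets are built for families of near-identical genes, so HLA-DRB1 and HLA-DPB1 values may include relatives. In WM793, asparagine synthetase ASNS went from 965 to 83.7 with DAC, against 649 to 391 in 1205-Lu, and ICA1, BICRAL and F10 had log2 changes of -3.02, -2.65 and -2.59, all with treated values under 3. The difference between the responses has no test with 1 array per group.

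Between the lines, 1205-Lu lacked most of the signal of CDKN2A, the cyclin-dependent kinase inhibitor locus, which stood at 474 and 210 on the untreated and treated WM793 arrays and at 2.27 and 5.63 on those of 1205-Lu. GPNMB, a melanosomal glycoprotein, stood at 82.4 and 57.4 against 3.13 and 2.30, and BST2, an interferon-induced antiviral protein, at 313 and 795 against 8.62 and 80.6. IL6 was at 274 and 393 against 26.1 and 104. Higher in 1205-Lu were the angiogenic factor VEGFA, at 44.3 and 36.9 against 5.62 and 6.17, the neuronal enolase ENO2, at 116 and 261 against 8.10 and 31.4, and the growth factor TGFA, at 46.2 and 45.3 against 5.88 and 8.87.

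Further genes lower in 1205-Lu, with the log2 difference of the untreated and of the treated pair, were CYBA (-6.89 and -1.48), KYNU (-2.71 and -5.13), SOX4 (-2.07 and -4.45), CHN1 (-3.66 and -2.39), PLA2G4A (-2.67 and -2.74) and DCAF8 (-3.07 and -2.26). Several of the 1205-Lu values were dim, and with the floor at 20 the differences were -4.50 and -1.48 for CYBA, -2.36 and -2.19 for KYNU, -0.15 and -1.33 for SOX4, -2.43 and -1.39 for CHN1, -0.64 and -0.44 for PLA2G4A and -0.26 and -0.31 for DCAF8. AKR1C1, SLC26A2, VIPR1, COL1A2 and IFIT1 were lower with a 1205-Lu value at the floor. Further genes higher were TBXAS1 (2.65 and 4.44), PTPRN2 (4.37 and 2.21), CRMP1 (3.83 and 2.64), ITPR1 (1.95 and 3.56), the AP-1 subunit FOSL1 (4.11 and 1.27), EMP1 (3.40 and 1.91) and UFM1 (3.50 and 1.64). With the floor at 20, TBXAS1, FOSL1 and EMP1 stayed past 2-fold in both pairs, and PTPRN2, CRMP1, ITPR1, UFM1 and VEGFA did not. SERPINA5, FOXO1, RORA, TFDP1 and DTNA were higher with a WM793 value at the floor.

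The interferon list was lower in 1205-Lu, with a median log2 difference of -0.998 untreated and -0.62 treated (percentile 0 in each), and 11 of 41 members were past 2-fold lower in both pairs, IFI44 (-2.22 and -2.81) and IFIT3 (-1.39 and -3.81) among them. limma passed 0 members over all genes and 12 adjusted over the list alone. In camera 4 lists were lower in 1205-Lu: interferon (adjusted p 6.7e-08), melanocyte differentiation (0.031), fibroblast and stromal markers (0.031) and cancer-testis antigens (0.035). Each had adjusted p = 0.83 with an estimated correlation, where 1 residual degree of freedom lets hardly any list pass. Melanocyte genes past 2-fold lower in both pairs were GPNMB, ERBB3 (-1.69 and -2.53) and APOE (-1.17 and -1.83), 3 of 21. Fibroblast markers had 3 of 19 (COL1A2, TAGLN and MFAP5), and cancer-testis antigens 3 of 12, MAGEA1 (-1.18 and -2.97) and MAGEA11 (-2.47 and -1.63) among them. The cancer-testis median was -0.23 in the untreated pair (percentile 16.6, 3 members past 2-fold higher and 3 lower) and -1.26 in the treated pair (percentile 0, 0 higher and 7 lower). The melanocyte medians were -0.33 and -0.44, and the fibroblast medians -0.86 and -0.38. Genes higher in both pairs included GADD45A (1.99 and 1.83), CCNB1 (1.18 and 2.57) and COL5A1 (2.03 and the floor in WM793 against 7.25 and 14.7 in 1205-Lu), while CCN2 (-1.87 and -3.33), CDH2 (-1.12 and -2.91), PTGS2 (-2.38 and -1.77) and the imprinted MEST (-1.70 and -1.61) were lower.

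By size, 598 genes were higher and 589 lower in untreated 1205-Lu than in untreated WM793, and 598 and 525 in the treated pair. Both pairs shared 166 higher genes (76.1 for independent lists) and 162 lower genes (65.8), and 104 went opposite ways (142). limma called 0 genes in either direction for the line, with a lowest adjusted p of 0.066, shared by GPNMB, AKR1C1 and CDKN2A, and had 290 higher and 262 lower at an unadjusted p under 0.05. With a variance prior that follows intensity limma called 7 higher and 14 lower. Values as deposited gave 496 higher and 669 lower in the treated pair (42.6% higher, against 53.3%), with a median of all genes of -0.13, against 0.013. With a floor at intensity 20 the counts in both pairs were 48 higher and 48 lower.

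**Figure D3:**
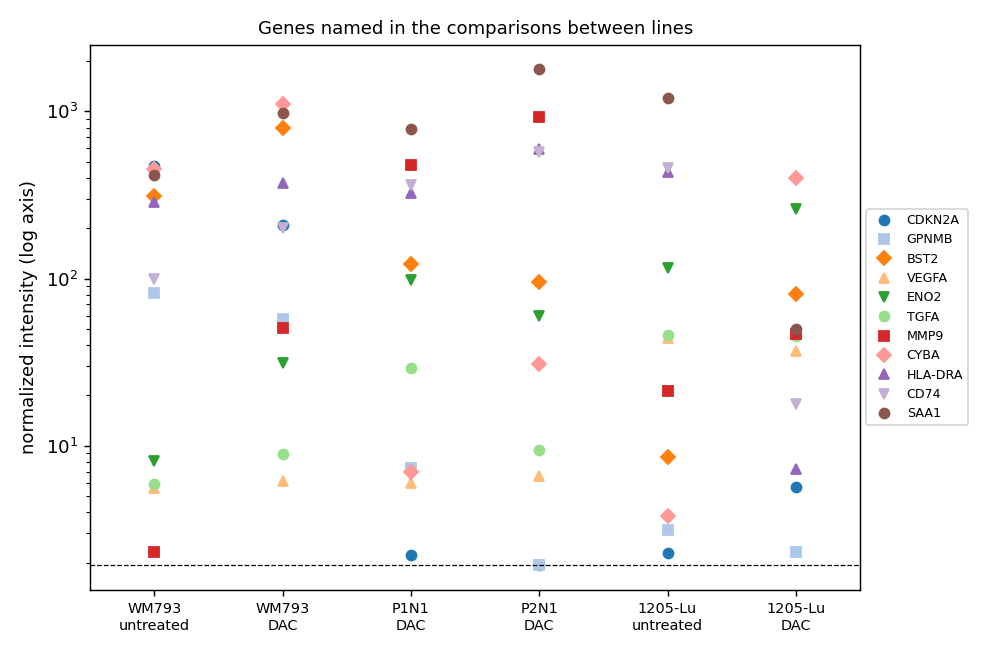
Normalized intensity (log axis) of 11 genes named in the comparisons, on each of the 6 arrays, with the floor of 1.93 as a dashed line; each point is 1 array. CDKN2A stands at 474 and 210 on the WM793 arrays and at no more than 5.63 on those of the derivatives, and VEGFA at 44.3 and 36.9 on the 1205-Lu arrays alone.

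Among treated cells, CDKN2A was at 2.22 in WM793-P1N1 and at the floor in WM793-P2N1, against 210 in WM793. MMP9 stood at 480 in WM793-P1N1 and 919 in WM793-P2N1, against 50.9 in WM793 and 46.6 in 1205-Lu. CYBA was at 6.95 and 30.7, against 1112 in WM793 and 400 in 1205-Lu. TBXAS1 (67.0 and 60.8 against 5.80), PTPRN2 (44.9 and 49.3 against 4.20) and the potassium channel KCNK1 (30.1 and 23.2 against 3.27) were higher in both WM793-P1N1 and WM793-P2N1, as was TERF1 (17.4 and 6.23 against 2.15), and CST4 was higher in WM793-P2N1 (58.5 against 6.67). COL1A2 was lower in both (6.82 and 2.38 against 45.7). PTGS2 stood at 454 in WM793-P1N1 and 34.1 in WM793-P2N1 against 552, TAC1 at 58.7 and 3.38 against 71.1, and MAPK8IP2 at 3.87 and 26.6 against 59.6.

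The interferon list was lower than in treated WM793 by medians of -1.59 in WM793-P1N1, with 28 of 41 members past 2-fold lower, and -1.57 in WM793-P2N1, with 22, both at percentile 0. Against untreated WM793 its median was -0.089 in treated WM793-P1N1 (4 members past 2-fold higher and 9 lower) and -0.24 in treated WM793-P2N1 (7 higher and 8 lower). Cell cycle genes had a median of 0.40 in WM793-P2N1 (percentile 100) against treated WM793, where their own median with DAC was -0.34. They had 0.17 in WM793-P1N1, which was -0.040 with median scaling. Fibroblast and stromal markers had a median of -0.92 in WM793-P2N1 (percentile 0), with 9 of 19 past 2-fold lower, and of -0.50 in WM793-P1N1 (percentile 2.16), which was -0.052 with values as deposited. Keratinocyte markers had a median of -0.60 in WM793-P1N1 (percentile 0.86) and of -0.081 in WM793-P2N1.

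In all, 586 genes were higher and 584 lower in WM793-P1N1 than in treated WM793, and 349 and 361 in WM793-P2N1. Values as deposited gave 808 and 481 in WM793-P1N1 (62.7% higher, against 50.1%), with a median of all genes of 0.15, against 0.024. In treated 1205-Lu, CA8 (98.0 against 7.22), CX3CL1 (43.1 against 2.97) and TNFRSF9 (54.5 against 5.60) were among the genes with the largest differences. All 3 derivatives shared 86 higher genes and 93 lower genes, CDKN2A, GPNMB, BST2, CYBA, ISG15, OAS1 and IFIT1 among the latter. Simulations without effect, which share the treated WM793 array, gave medians of 44 and 59 and at most 61 and 77, and independent lists 4.91 and 4.44. In the simulations the shared array gave counts far above those of independent lists. The observed counts passed the simulated maxima, by a margin that depends on the noise estimate. With the floor at 20, 11 genes were higher and 21 lower in all 3.

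Genes lower in untreated 1205-Lu than in untreated WM793 and higher again with DAC were counted as restored, 201 in all. TAC1, a tachykinin precursor, went from 79.8 in untreated WM793 to the floor in untreated 1205-Lu and to 57.2 with DAC. CYBA went from 452 to 3.81 and 400, MX1 from 83.5 to 7.90 and 328, MT1E from 35.1 to 4.90 and 159, and AZGP1 from 17.7 to 2.37 and 55.9. GAP43 reached 70.8 and TIMP4 109 from the floor, against 12.3 and 5.52 in untreated WM793. IFI27, ADM and ARC also met the rule, and 32 of the 201 were past 2-fold higher with DAC in WM793 too.

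The count shares the untreated 1205-Lu array between its conditions, and like the counts for both lines it rests on the label of the single treated 1205-Lu array. Simulations without effect gave a median of 95 and at most 112, and independent lists 66.3. The opposite pattern (higher in untreated 1205-Lu and lower with DAC) held 183 genes, against a simulated median of 116 and at most 145. Both counts passed their simulated maxima, so an excess of this kind is not particular to restored genes. On the untreated 1205-Lu array 65 of the 201 were at the floor, and with a floor at intensity 20 the count was 37. With the line difference taken from the treated arrays it was 37, against a simulated median of 3 and at most 7 without effect and 59.1 for independent lists. Both conditions of that count use the treated 1205-Lu array with opposite signs, which lowers it, so 37 against 59.1 does not speak against restored genes. Of 16 restored genes with other informative probe sets, 13 had these lower on the untreated 1205-Lu array (81.3%, exact 95% interval 54.4 to 96.0%), against 48.1% of all genes with several probe sets.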

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

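The tests of this part were chosen after the opposite changes in 1205-Lu had been seen. For 7 genes the change with DAC in 1205-Lu had the opposite sign from that in WM793 and the difference was among the largest. The difference was not tested, since each group is 1 array. The log2 change in 1205-Lu minus that in WM793 was 4.10 for the nitric oxide synthase NOS3, 4.02 for the TGF-beta binding protein LTBP1 and 3.997 for the complement protease C1S. It was -6.30 for HLA-DRA, -5.83 for SAA1, -5.70 for CD74 and -5.55 for GAS6, a ligand of TAM receptors. HLA-DRA changed little in WM793 (0.39), where HLA-DRB1 and HLA-DPB1 were slightly lower with DAC (-0.27 and -0.46), so its opposite sign carries little weight. With the floor at intensity 20, LTBP1 had no change in either line and NOS3 none in 1205-Lu, so their differences rest on dim signal.

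Other class II genes, looked up after these values were seen, were also lower with DAC in 1205-Lu. HLA-DPA1 went from 104 to 15.2 there and from 63.7 to 65.1 in WM793, and HLA-DMA from 38.1 to 14.7 and from 10.02 to 39.3. On the treated WM793-P1N1 and WM793-P2N1 arrays HLA-DRA stood at 326 and 598 and SAA1 at 780 and 1782. B2M, the light chain of class I molecules, stood at 795 and 811 on the untreated and treated 1205-Lu arrays.

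The lower HLA-DRA, CD74, SAA1 and MAGEA12 signal on a single array could come from RNA of another line under that label. Of 29 genes that set untreated 1205-Lu apart from the 4 arrays of WM793, WM793-P1N1 and WM793-P2N1 by 4-fold, the treated 1205-Lu array shared 8 (27.6%, exact 95% interval 12.7 to 47.2%). The highest such share between arrays of different lines was 44.4%, from untreated 1205-Lu to untreated WM793, so the share met what had been written for a wrong label. In a comparison added after that share was seen, however, the treated WM793 array shared only 22.7% of the genes that set untreated WM793 apart, so the test would have failed an array that nothing else calls into doubt, and a wrong label cannot be told apart here from a response of 1205-Lu to DAC. Other values do not settle it. VEGFA stood at 44.3 and 36.9 on the 1205-Lu arrays and at no more than 6.58 on the others. Genes that set the treated 1205-Lu array apart were shared most by untreated 1205-Lu (21.6%, exact 95% interval 9.8 to 38.2%, others at most 14.7%). Across probe sets the rank correlation of the treated 1205-Lu array was 0.908 with treated WM793-P2N1 and 0.904 with treated WM793, against 0.901 with untreated 1205-Lu. That order decides nothing, since the treated WM793 array showed it too. Its correlation was 0.931 with treated WM793-P2N1 and 0.904 with treated 1205-Lu, against 0.900 with untreated WM793.

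The counts of genes past 2-fold with DAC in both lines, the restored genes and the treated pair of lines use the treated 1205-Lu array. So do the interferon median of 0.90 with DAC in 1205-Lu and the 15 list members higher in both lines. The genes shared by the treated derivatives use it too. Every limma and camera result for DAC and for the line, the call of IFI27 among them, also includes that array. A doubt about its label extends to all these results.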

How the results depend on the processing

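The floor at intensity 20 and the counts from a pair alone were chosen after the data were seen; the other alternatives were set beforehand. No result changed sign past its threshold. Counts moved with the floor and the fold threshold because fewer or more genes can pass, and for other moves the cause was not tested. Signal over background limits the 2-fold counts, which were lower with the floor at the 40th percentile and lower again at 20. Of the named results, 100 kept their side of 2-fold at intensity 20 and 71 did not.

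For genes higher and lower with DAC in WM793 the counts were 355 and 281 with the floor at the 40th percentile, 278 and 164 at 3-fold, 1019 and 1122 at 1.5-fold and 167 and 142 with the floor at 20. In 1205-Lu they were 335 and 296, 234 and 182, 1077 and 1017, and 193 and 157. In both lines they were 86 and 63, 50 and 19, 399 and 344, and 43 and 30, and 89 and 74 with all arrays above the floor. For 1205-Lu against WM793 in both pairs they were 99 and 95, 41 and 54, 426 and 372, and 48 and 48. Restored genes were 91, 74, 419 and 37, and 37 with the treated line difference. Genes past the threshold, both directions together, were 632, 487, 2181 and 286 for the untreated lines, 704, 448, 2106 and 380 for the treated lines, 559, 487, 2119 and 224 for WM793-P1N1 and 312, 262, 1604 and 138 for WM793-P2N1. A pair alone gave 562 to 615 higher and 525 to 542 lower for DAC, and 598 to 598 higher and 525 to 589 lower for the line.

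limma called 0 genes higher with DAC under median scaling, the floor at the 10th percentile, all arrays above the floor, no filter and no line block, 2 with all 6 arrays and 3 with an intensity trend. For the line it called 5 higher and 7 lower with the floor at the 40th percentile, 7 and 14 with an intensity trend, and 3, 2 and 3 lower with values as deposited, all arrays above the floor and the mean of probe sets.

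With an estimated correlation 6 list calls were lost, at unchanged medians: interferon (1.22 for DAC, -0.94 for the line), fibroblast (0.81 and -0.62), cancer-testis (-0.41) and melanocyte (-0.43). That setting rests on 1 residual degree of freedom, at which hardly any list can pass, so these losses decide nothing. The fibroblast DAC call was also lost under median scaling (0.89) and with floors at the 10th percentile (0.81) and 20 (0.52), and its line call with floors at the 40th percentile (-0.36) and 20 (-0.44). The cancer-testis line call was lost with floors at the 10th percentile (-0.31) and 20 (-0.34), and the melanocyte call at 20 (-0.31). Ribosomal proteins passed with DAC under median scaling (-0.46), values as deposited (-0.59) and floors at the 40th percentile (-0.29) and 20 (-0.29), and keratinocyte markers with the floor at the 40th percentile (0.40).

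Within WM793 and 1205-Lu alone the DAC medians ran from -0.67 to -0.063 for cancer-testis antigens, 0.90 to 1.34 for interferon, -0.31 to 0.42 for antigen presentation, 0.012 to 0.094 for genes often methylated, 0.29 to 0.49 for p53 targets, -0.45 to -0.31 for methylation machinery, -0.13 to 0.0016 for metallothioneins, -0.36 to -0.32 for deoxycytidine genes, -0.17 to 0.064 for growth factors, -0.13 to 0.042 for leukocyte markers and 0.00 to 0.54 for fibroblast markers.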

Other observations

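The tests on the interferon pattern were chosen after the result was seen. Some genes were high on the treated arrays of WM793, WM793-P1N1 and WM793-P2N1. S100A9, a calcium-binding alarmin, was at the floor on the untreated WM793 array, at 120 on the treated one, and at 93.3 and 263 in treated WM793-P1N1 and WM793-P2N1, but at 2.27 and the floor on the 1205-Lu arrays. S100A7 was at the floor in untreated WM793, at 38.8 treated, and at 13.4 and 19.8 in the treated WM793-P1N1 and WM793-P2N1 cells. H19 stood at 186 and 278, IGFBP5 at 215 and 30.3 and TMSB4X at 147 and 150 in treated WM793-P1N1 and WM793-P2N1, where untreated WM793 was at the floor for each. ASNS, at 965 in untreated WM793, stood at 232 and 74.3 in those cells.

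The higher interferon list with DAC in both lines is open to the lower actin 3′ to 5′ ratio of the treated arrays. A comparison of the untreated arrays, where 1205-Lu had the lower ratio and a list median of -0.998 against WM793, decides nothing, since the lines also differed in the list on the treated arrays (-0.62). RNA quality and a response to DAC therefore cannot be told apart here. Scaling does not account for the pattern, since the smaller of the line medians was 0.88 over the other scalings. The response of WM793-P1N1 and WM793-P2N1 was not tested, since their untreated cells were not analysed here.

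The genes past 2-fold with DAC in both lines could reflect errors of single probe sets. Where higher genes had other probe sets, these were also higher on average for 10 of 11 genes (90.9%, exact 95% interval 58.7 to 99.8%). The share was 47.0% for all genes with several probe sets. This argues against probe error for those 11 genes as a set. The rest of the 152 higher genes could not be checked in this way. For lower genes it was 7 of 9 (77.8%, exact 95% interval 39.99 to 97.2%), an interval that holds 50%, so probe error stays open for FST, NR4A2 and the other lower genes. Lower genes were long, with a median of 47.1 kb against 14.2 kb for higher genes and 26.7 kb for all, but across genes the rank correlation of change with length was -0.14 in WM793, past the bound set for a length effect, and -0.048 in 1205-Lu, within the bounds set against it. With the lines on opposite sides, length and a response to DAC cannot be told apart for the lower genes.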
